A study of Mus musculus with 18 samples.

How the data were processed

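RNA was measured in 18 mouse libraries: LT-HSC, ST-HSC and MP in 5 conditions each and fibroblasts in 3. The blood libraries came from 25 cells each, amplified by oligo-dT priming and PCR, and the fibroblast libraries from RNA prepared by the standard Illumina route, so fibroblasts and blood cells differ in library method as well as in cell type. The values are the deposited FPKM, 1 per gene and library, made per the submitters' processing notes with TopHat and Cufflinks on genome build mm9; tool versions and the annotation are not given in the sources used here. The unit was read from the values. Because the values are on mm9 and the reference annotation used for gene classes and names (GENCODE M21) is on another build, no coordinates are given. Depth is unknown: low FPKM values were checked and were not whole multiples of a step, so counts could not be recovered, and no interval or detection limit that needs depth is given. A value of 0 can be a failed estimate as well as no reads, so such values are described as listed at 0. Gapdh, Rpl3 and Rps6, which all cells use, were listed at 0 in some libraries and at no more than 22.6 FPKM in any, so low values of genes with many near copies cannot be read as low expression. Where every library of a group is at 0, a fitted log2 difference depends on the value added before the log.

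The table held 36818 entries with 36655 distinct symbols, of which 17955 were above 0 in any library. The 158 symbols on several entries were summed to 1 value per symbol. Libraries were grouped by cell type and title, D or N. The doxycycline field conflicts with the titles in all 6 N libraries, and the titles were used because the series design describes N as the culture control. Comparisons, alternatives, 28 gene lists with 951 members, tests and the rule for naming genes were set before the data were examined. Of the list members, 1 was not found and 1 was matched by its Ensembl ID.

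Values were log2(FPKM + 1). Log2 differences therefore depend on the added 1 wherever a group lies near 0. Genes with a mean FPKM of at least 1 over the libraries of a fit were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options), with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. D was compared with N with a term for each of the 6 pairs of cell type and day, leaving 5 residual degrees of freedom. Interaction fits tested whether that difference changed between days or between MP and the stem cells. N cultures, and D cultures, were compared with uncultured cells with cell type as block, 4N with 2N likewise, and MP with the stem cells and ST-HSC with LT-HSC with condition as block. The fibroblast change from uncultured to D was compared with that of the blood cells. All these tests take single libraries of different types or days as replicates of each other.

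Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over the lists of a fit. For D against N an exact two-sided sign-flip test over the list medians of the 6 pairs (64 flips) was added. Fibroblast libraries alone were described without a test: genes at FPKM 10 or more in at least 1 library, a 4-fold change at both days, and list medians (mean of both days) against 10000 random lists drawn in 20 bins of expression. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

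Genes were named by rank: the 10 largest rises and the 10 largest falls among genes past the threshold that moved the same way in every block, filled up to 5 by smallest p where fewer passed. For the interaction fits, ST-HSC against LT-HSC and 4N against 2N the number was 5 each way. For fibroblasts alone it was 10 each way by the mean of both days, same direction at both. The 4 factors and up to 4 members of each list described were also named. Some genes that this rule names are not reported here. Genes named outside the rule are said to be chosen after their values were seen. These are the overlap examples, the genes of uncultured LT-HSC and of ST-HSC D libraries, the late granule genes in 2N, Gapdh, Rpl3 and Rps6, Nanog as a pluripotency marker, and the genes given per library for the closing observations.

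The fits were tested on simulated data in which 200 genes were shifted, 50 at each of 4 sizes. Noise was drawn independently for each gene from the fitted variances, and a shift was the same in every block. The shares below hold for such data and need not hold for the real libraries. At a log2 change of 2 the share found was 60% for D against N, 48% for N against uncultured, 32% for 4N against 2N, 58% for MP against stem cells, 38% for ST-HSC against LT-HSC and 32% for D against uncultured. It was 6% for the day interaction and 2% both for the MP interaction and for fibroblasts against blood. At a log2 change of 4 these shares were 88%, 78%, 78%, 78%, 88%, 82%, 64%, 54% and 42% in the same order. At 1 they were 18% or less, and at 6 they were 62% to 86%. Unchanged genes made up 2.94% to 8.7% of calls, except 42.4% for fibroblasts against blood (39 genes), where genes at the floor of 0 cannot fall; without that floor it was 4.76%. Camera called a shifted list of 30 genes in all 9 fits and 0 of 20 unshifted ones. Lists of correlated genes were not simulated, so this cannot show how often camera calls such a list in error. For D against N, the estimated correlation within the real lists ran from -0.113 (pluripotency genes) to 0.676 (ribosome biogenesis genes). Of 20 unshifted lists, 1 lay outside 95% of the random fibroblast lists.

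Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a mean FPKM of at least 5, quantile normalization, median-of-ratios scaling, limma without trend and robust options, each block left out in turn, each day's pairs alone, no pair term, cell type as the unit, and the uncultured libraries excluded. Added after seeing the data were protein-coding genes only, day 2 only, D against N without both ST-HSC pairs, and the interaction for ST-HSC and for LT-HSC. Splice variants and transgene transcripts were not analysed here, since the values are summed per gene.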

Results

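RNA sequencing measured gene expression in 18 libraries from C57BL/6 mice grown entirely from induced pluripotent stem cells. These mice carry a doxycycline-inducible set of the reprogramming factors Oct4 (gene Pou5f1), Sox2, Klf4 and c-Myc (gene Myc). Blood-forming cells were long-term haematopoietic stem cells (LT-HSC), short-term haematopoietic stem cells (ST-HSC) and myeloid progenitors (MP), and fibroblasts gave a second lineage. Each blood cell type gave 5 libraries: uncultured (0), and cultured for 2 or 4 days under the titles N (2N, 4N) or D (2D, 4D). Fibroblasts gave 3 libraries (0, 2D and 4D). By the series design, D libraries were from cells given doxycycline and N libraries from cells cultured without it, although the doxycycline field of all 6 N libraries reads yes; the titles are used here. Each condition was a single library, so there were no replicates, and p-values measure the spread between cell types and days used as blocks.

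The blood libraries were made from 25 hand-picked cells each by amplification, and the fibroblast libraries by the standard Illumina route. The deposited values are FPKM, and read depth is unknown. Total FPKM ranged from 677649 to 767866 in the 15 blood libraries, with 10478 to 11365 genes at FPKM 1 or more. In the 3 fibroblast libraries total FPKM ranged from 524225 to 572069, with 11833 to 12425 genes at FPKM 1 or more. The 100 highest genes took 27.61% to 34.27% of the total in blood libraries and 24.02% to 24.84% in fibroblasts. Between libraries, the correlation across genes (which are not independent replicates) had a median of 0.859 for blood libraries of the same condition and 0.788 for blood libraries of the same cell type. The first principal component of the blood libraries held 28.05% of the variance. Uncultured libraries lay at -104.87 to -59.28 on it, N libraries at -31.31 to -19.38 and D libraries at 21.19 to 107.63.

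**Figure D1:**
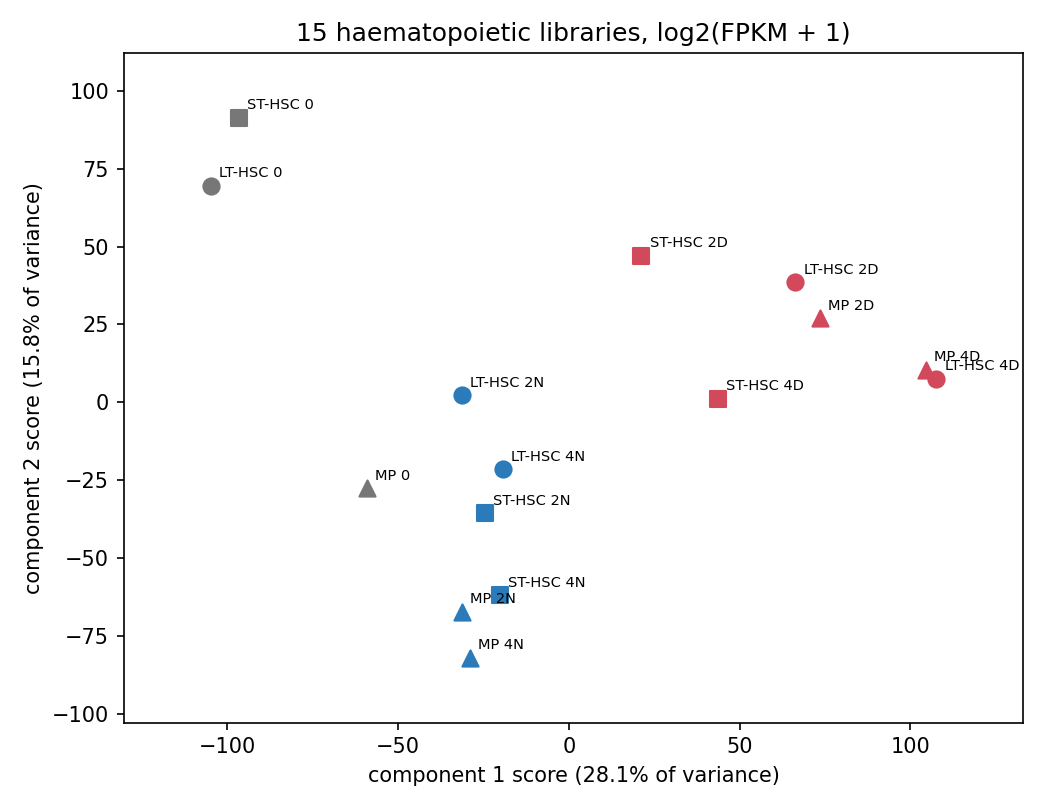
Scores of the 15 blood libraries on the first (x) and second (y) principal components of log2(FPKM + 1), with 28.05% and 15.77% of the variance; each point is 1 library. On the first component the 6 D libraries lie at 21.19 or above, the 6 N libraries at -31.31 to -19.38 and the 3 uncultured libraries at -59.28 or below.

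The levels of the 4 factors came first, since they are what doxycycline was meant to switch on. Sox2 (ENSMUSG00000074637), a transcription factor of pluripotent and neural stem cells, was listed at 0 to 1.496 FPKM in the 6 N libraries and at 15.6 to 61.3 in the 6 D libraries. Its fitted log2 difference between D and N was 4.64 ± 0.445 (SE; limma adjusted p = 4.09e-04). In fibroblasts Sox2 went from 1.77 FPKM uncultured to 124 at 2D and 74.2 at 4D. Pou5f1 (ENSMUSG00000024406), the master regulator of the pluripotent state, was listed at 0 in most blood libraries, the exceptions being LT-HSC 2D (2.04), ST-HSC 2D (2.07) and MP 4D (2.34), and at 29.2 and 23.4 FPKM in fibroblasts at 2D and 4D. Myc (ENSMUSG00000022346), a driver of growth and division, was lower in D than in N at day 2 in each blood cell type (67.4 against 188 FPKM in LT-HSC, 47.6 against 284 in ST-HSC, 45.5 against 319 in MP). At day 4 Myc in D and N stood at 189 against 291 FPKM in LT-HSC, 149 against 205 in ST-HSC and, the other way, 133 against 102 in MP. Across both days its difference of -1.25 did not pass the threshold (limma adjusted p = 0.0842). Klf4 (ENSMUSG00000003032), a regulator of epithelial and myeloid genes, stood at 214 and 240 FPKM in uncultured LT-HSC and ST-HSC and at 11.2 or less in all D blood libraries, and its D and N levels did not separate (log2 1.26, adjusted p = 0.28). Nanog, which marks established pluripotency, was listed at 0 in all 18 libraries. FPKM does not tell transgene from endogenous transcripts.

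**Figure D2:**
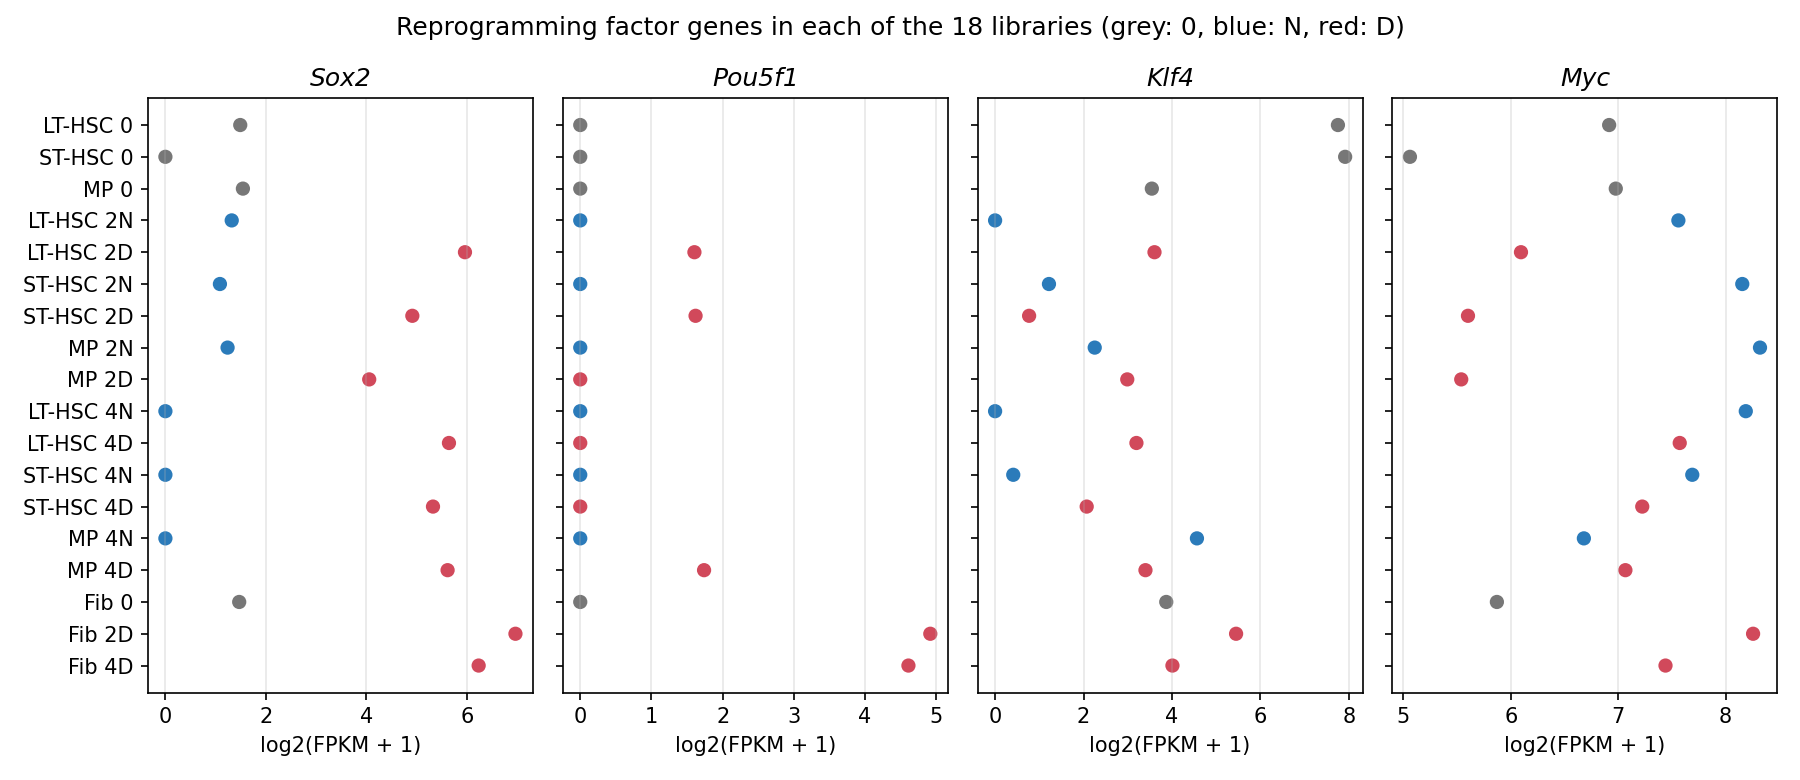
Expression of the 4 reprogramming factors (x axis, log2 of FPKM + 1) in each of the 18 libraries (y axis, by cell type and condition). Sox2 is at 15.6 FPKM or more in every D library of blood cells and at 1.496 or less in every N library.

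The comparison of D with N cultures, matched for cell type and day, asks what factor induction did beyond culture. In limma fitted to 6 pairs, 1099 of 12254 genes passed an adjusted p of 0.05, 555 higher and 544 lower in D, and 920 of them moved the same way in all 6 pairs. Stmn2, a microtubule regulator of growing neurites, rose by 8.07 ± 0.446 log2 units (adjusted p = 3.56e-05), from 0 to 5.34 FPKM in N to 105 to 1270 in D. Mobp, a myelin protein of oligodendrocytes, was listed at 0 in every N library and at 61.8 to 216 FPKM in D (adjusted p = 2.41e-05). The same held for the neuropeptide Npy, at 0 in every N library and 29.6 to 243 FPKM in D (adjusted p = 8.63e-05). Dpysl3, which guides axon growth, rose by 6.46 (adjusted p = 2.2e-04). Helt and Sox21, transcription factors of the developing nervous system, rose by 6.16 and 6.10 (adjusted p = 6.89e-05 and 3.56e-05). The embryonic beta-like globin Hbb-y rose by 8.35 ± 1.003 (adjusted p = 0.00202), reaching 63.1 to 6887 FPKM. The remaining large rises were the retinol dehydrogenase Adh7 (6.47), the liver-secreted protease inhibitor Fetub (6.13) and the imprinted fetal gene Mest (5.79), with adjusted p of 6.89e-05, 0.00166 and 2.2e-04.

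The falls included many genes of myeloid cells. Prtn3, a serine protease of neutrophil granules, fell by 7.12 ± 0.709 log2 units (adjusted p = 7.77e-04), in MP from 15200 and 13400 FPKM in N to at most 70.5 in any D library. Myeloperoxidase (Mpo) fell by 6.25 ± 1.16 (adjusted p = 0.0138) and cathepsin G (Ctsg) by 6.09 ± 1.26 (adjusted p = 0.0203). Both calls ended without the MP day 2 pair (adjusted p = 0.0542 for Mpo and 0.0591 for Ctsg), and that of Ctsg also without the MP day 4 pair (0.0585). The remaining 18 of the 20 genes named by rank kept their calls with each pair left out. Cd37, a tetraspanin of leukocytes, fell by 5.88 ± 0.415 (adjusted p = 1.06e-04), from 24.3 to 255 FPKM in N to 3.59 or less in D. The leukocyte phosphatase Ptpn7 fell by 5.77 (adjusted p = 1.16e-04) and the NADPH oxidase subunit Ncf4 by 5.93 (adjusted p = 0.0102). The activating adaptor Tyrobp fell by 5.68, the granule protein Nkg7 by 5.63, the macrophage factor Tcfec by 5.38 and the chemokine Ccl9 by 5.34, with adjusted p of 0.00406, 0.00151, 0.00174 and 0.00168. The number of genes past the threshold was 678 without the LT-HSC day 2 pair, 730 without LT-HSC day 4, 529 without MP day 2 and 630 without MP day 4.

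Among gene lists fixed beforehand, myeloid differentiation genes, which include granule proteases and the receptors and factors of granulocytes and monocytes, fell most broadly. Of 46 tested, 26 fell and 0 rose (36 fell and 0 rose when adjusted over the list alone), with a median of -3.28. The list median was below 0 in 6 of 6 pairs, from -1.41 in LT-HSC day 4 to -5.48 in MP day 4. An exact two-sided sign-flip test over the 6 pairs gave p = 0.0312, the smallest it can give, and 0.218 after adjustment over the lists. Camera with its preset correlation gave 3.46e-21, and adjusted p = 0.414 with an estimated correlation. Of all 28 lists, 12 passed camera with the preset correlation, 5 higher and 7 lower; none passed with an estimated one, and 8 passed fry, which does not compare a list with other genes.

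Other blood lists fell in part. The list medians of mast cell, megakaryocyte and macrophage genes were below 0 in 3 of 6 pairs (exact sign-flip p = 0.25 each, adjusted 0.368). Those of JAK-STAT and interferon genes were below 0 in 5 and 4 pairs (exact sign-flip p = 0.0625 and 0.188, adjusted 0.263 and 0.368). Mast cell and basophil markers had 4 of 16 members lower and 0 higher (6 and 0 adjusted over the list alone; camera 2.81e-05, and adjusted p = 0.504 with an estimated correlation), among them the basophil protease Mcpt8 (listed at 0 in every D library), the granule proteoglycan core Srgn (-4.32) and the cytokine receptor chain Csf2rb2 (-3.60). Of 17 megakaryocyte and platelet genes, 2 fell and 1 rose (7 and 1 adjusted over the list alone; camera 3.77e-04, and adjusted p = 0.611 with an estimated correlation). The platelet integrin Itga2b fell by 4.40 and the platelet substrate Plek by 4.17, while the protease inhibitor Serpine2 rose by 2.99. JAK-STAT receptors and feedback genes, which carry cytokine signals, had 6 of 26 lower and 0 higher both over all genes and adjusted over the list alone (camera 1e-04, and adjusted p = 0.611 with an estimated correlation). These included the feedback inhibitor Cish (-4.41), the shared receptor chain Csf2rb (-4.20), the interleukin-4 receptor Il4ra (-2.76) and the kinase Pim1 (-2.50). Interferon response genes had 3 of 27 lower (4 lower and 1 higher adjusted over the list alone; camera 0.0111, and adjusted p = 0.626 with an estimated correlation), all of antigen processing: Psmb9 (-3.44), Psmb8 (-2.94) and Tap1 (-1.92). That list's call ended without the LT-HSC day 4 pair (0.0805) or the MP day 4 pair (0.0836). Of 13 macrophage and dendritic markers, 1 fell (the same adjusted over the list alone), H2-Aa of antigen presentation (-2.94). Its list call (camera 0.0259, and adjusted p = 0.611 with an estimated correlation) ended without ST-HSC day 4 (0.105), MP day 2 (0.0611) or MP day 4 (0.19).

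TGF-beta pathway genes and targets had 10 of 28 members higher and 0 lower (10 and 1 adjusted over the list alone), with a median of 0.76 that was above 0 in 6 of 6 pairs (exact sign-flip p = 0.0312, adjusted 0.218; camera 0.00206, and adjusted p = 0.15 with an estimated correlation). Id3, an inhibitor of differentiation factors and a target of this pathway, rose by 5.11 ± 0.53 (adjusted p = 6.09e-04), the receptor Acvr1 by 3.70, the latent TGF-beta binder Ltbp1 by 3.27, and the ligand Tgfb2 was listed at 0 in every N library and at 1.341 to 24.9 FPKM in D. WNT pathway genes had 5 of 20 higher and 0 lower (7 and 0 adjusted over the list alone; median 0.90, above 0 in 6 of 6 pairs with the same exact p; camera 6e-04, and adjusted p = 0.15 with an estimated correlation). They included the transcription factor Tcf7l2 (3.10), the receptor Fzd1 (2.66), and the transcription factors Tcf7l1 and Lef1, which were listed at 0 in every N library. Epithelial genes had 8 of 23 higher and 0 lower (10 and 2 adjusted over the list alone; median 1.49; camera 0.00608, and adjusted p = 0.504 with an estimated correlation). Desmoplakin (Dsp, 3.42), the desmosome-associated Perp (2.83) and the tight-junction proteins Ocln (2.70) and Cldn3 (listed at 0 in every N library) were among them. The epithelial list median was above 0 in 4 of 6 pairs (exact sign-flip p = 0.125, adjusted 0.318) and at 0 in MP day 4 and ST-HSC day 4. The list call ended without the ST-HSC day 2 pair (0.0573). Mesenchymal genes had 3 of 18 higher and 1 lower (4 and 1 adjusted over the list alone; median above 0 in 6 of 6 pairs, exact sign-flip p = 0.0312, adjusted 0.218; camera 0.108), the matrix genes Sparc (3.55), Cyr61 (listed at 0 in every N library) and Fbn1 (1.73) rising and the surface antigen Thy1 falling (-2.31).

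**Figure D3:**
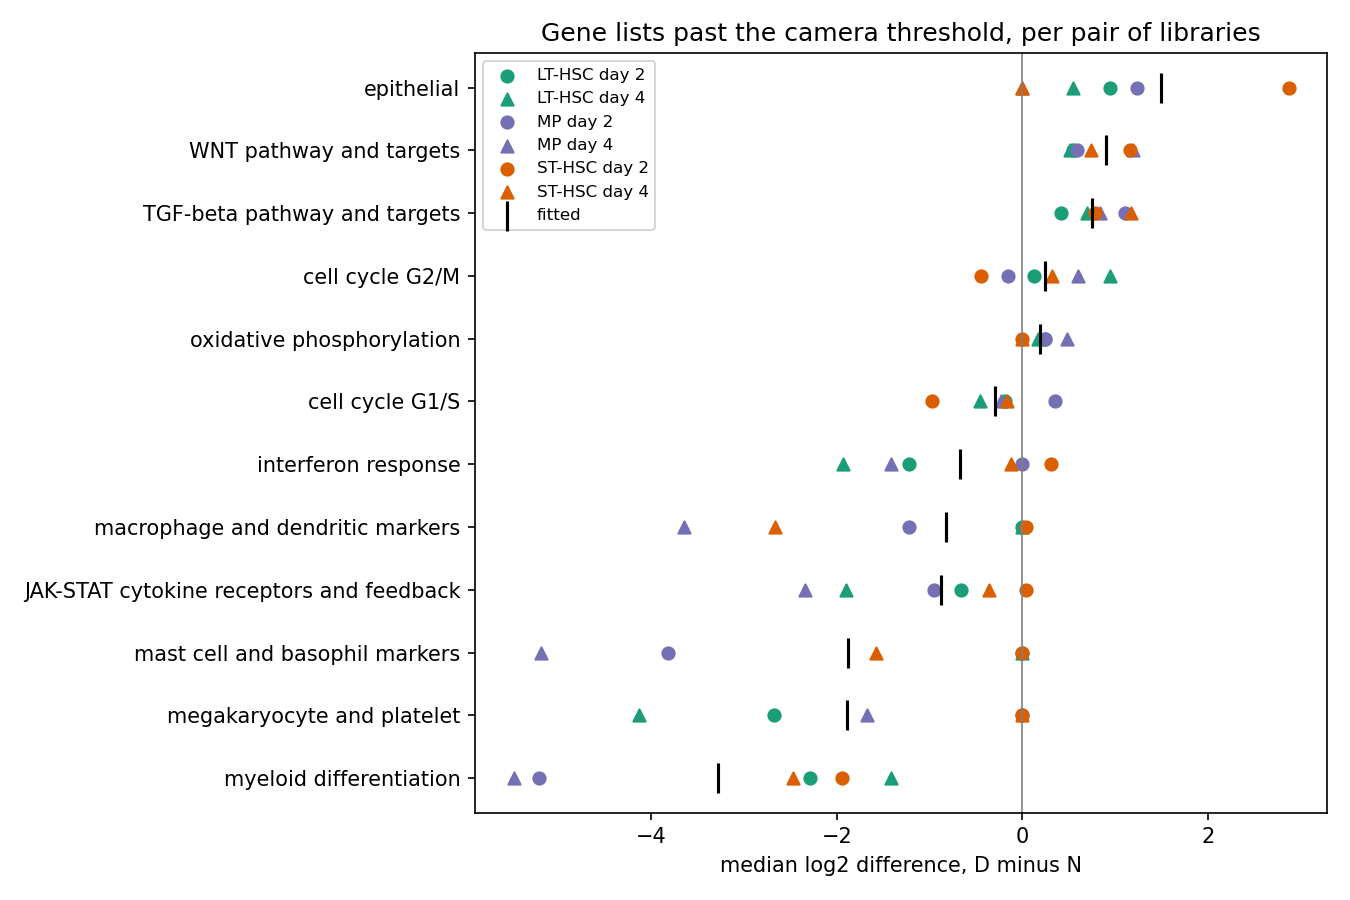
Median log2 difference between D and N (x axis) of each gene list past camera's threshold (y axis), with 1 point per pair of libraries and a mark for the fitted value. The myeloid list lies below 0 in 6 of 6 pairs, from -1.41 to -5.48, and the TGF-beta and WNT lists above 0 in 6 of 6.

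Stem and progenitor transcription factors moved both ways. Of 24, 4 rose and 5 fell (7 and 9 adjusted over the list alone; camera 0.389). Gfi1b, needed for erythroid and platelet development, fell by 3.85, the progenitor factor Myb by 3.31 and the early blood factor Lyl1 by 3.23, while Mecom, needed for stem cell maintenance, rose by 2.48. Of 30 HSC surface and signature genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone; camera 0.108), with the surface proteins Cd34, Cd48 and Gpr56 at -4.37, -3.84 and -3.71. Among 32 p53 targets, 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera 0.335), including the antiproliferative Btg2 (2.47) and the Akt inhibitor Phlda3 (2.29). Of 26 immediate early and stress genes, 2 rose (4 adjusted over the list alone; camera 0.284), the AP-1 subunit Jun (2.61) and the nuclear receptor Nr4a1 (2.19). Of 9 pluripotency genes, 1 rose (1 higher and 1 lower adjusted over the list alone; camera 0.626), the self-renewal factor Klf5 (3.93, adjusted p = 8.83e-04). Of the 3 factors tested, Sox2 was called (1 higher and 1 lower adjusted over the list alone; camera 0.284).

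Growth and metabolism lists moved little on average over the pairs, but single pairs went opposite ways in some of them. The median of ribosome biogenesis genes ran from -1.27 in ST-HSC day 2 to 0.595 in LT-HSC day 2. That of G2/M genes ran from -0.443 in ST-HSC day 2 to 0.946 in LT-HSC day 4, and that of G1/S genes from -0.978 in ST-HSC day 2 to 0.357 in MP day 2. Oxidative phosphorylation genes had 3 of 50 higher (0 adjusted over the list alone; median 0.19; camera 0.00867, and adjusted p = 0.611 with an estimated correlation; 0.0592 without MP day 4), among them Ndufa4 of the respiratory chain (0.84). For G1/S genes 1 of 46 fell (0 adjusted over the list alone; median -0.30; camera 0.00867, and adjusted p = 0.736 with an estimated correlation; 0.257 without ST-HSC day 2), the replication helicase subunit Mcm3 (-0.73). None of 45 G2/M genes passed limma's threshold or the list's own (median 0.24; camera 0.0253, and adjusted p = 0.739 with an estimated correlation). That list call ended without LT-HSC day 4 (0.388), ST-HSC day 4 (0.0546) or MP day 4 (0.111). Glycolysis genes had 2 of 24 lower (3 adjusted over the list alone; camera 0.122), hexokinase Hk1 (-1.43) and triosephosphate isomerase Tpi1 (-0.86). None of 45 ribosome biogenesis genes passed limma's threshold (camera 0.924). Cytosolic ribosomal proteins had 1 of 51 higher, Rpl5 (1.52), and 1 lower, Rpl19 (-1.20), with 0 adjusted over the list alone (camera 0.692). Of 47 chromatin enzymes, the demethylase Kdm5b rose (1.81) and the deacetylase Hdac7 (-1.16) and the methyltransferase Dnmt1 (-0.87) fell (1 higher and 1 lower adjusted over the list alone; camera 0.924).

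The smallest lists had single calls. Of 8 fibroblast markers, 2 rose and 2 fell, the same adjusted over the list alone (camera 0.834), with the secreted Fstl1 at 5.66 and Igfbp7 at -4.31. Of 14 erythroid genes, 1 fell in both adjustments, the erythroid and platelet factor Nfe2 (-4.30; camera 0.268). Among 7 lymphoid markers 1 fell in both adjustments, the B-cell receptor chain Cd79b (-3.65; camera 0.821), and the list's median of 0.53 and mean of -0.17 differed in sign. Of 11 endothelial markers, 1 fell, the adhesion molecule Icam2 (-3.15), with 2 higher and 1 lower adjusted over the list alone (camera 0.33). Among 12 MAPK feedback and FGF genes 1 rose, the receptor Fgfr3 (2.77), with 1 higher and 1 lower adjusted over the list alone (camera 0.556).

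Whether the D minus N difference changed from day 2 to day 4 was tested across the cell types. No gene passed in limma (511 at an unadjusted p under 0.05). Nearest by rank were Pax6, an eye and brain factor, at 4.85 (adjusted p = 0.989), and Ly6d, a lymphoid surface protein, at -6.09 (adjusted p = 0.877). Myc, lower in D at day 2, had a difference between days of 2.03 (adjusted p = 0.989). As lists, G2/M genes (median 0.84, camera 2.52e-11, and adjusted p = 0.585 with an estimated correlation) and ribosome biogenesis genes (0.68, camera 7.35e-09, and adjusted p = 0.72 with an estimated correlation) stood higher at day 4. Macrophage markers stood lower (-2.10, camera 2.28e-04, and adjusted p = 0.585 with an estimated correlation; 0.0604 without ST-HSC), with the antigen-presenting H2-Ab1 and H2-Aa passing when adjusted over the list alone. None of the 28 lists passed fry.

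Whether MP responded differently from the stem cells was tested next. The myeloid fall in log2 units was larger in MP, where most of these genes also started higher. No single gene passed in limma (1018 at an unadjusted p under 0.05, smallest adjusted p = 0.207; 1 gene without ST-HSC day 4), the nearest being neutrophil elastase Elane at -7.62 and Prtn3 at -4.24 (both 0.207), the oxidase subunit Ncf4 at -5.99 (0.231) and the receptor chain Csf2rb at -4.31 (0.26). Of 46 myeloid differentiation genes, 14 fell further in MP adjusted over the list alone and 0 over all genes. The list had a median difference of -3.49, with camera 1.38e-24, adjusted p = 0.0301 with an estimated correlation and fry 0.0173, and kept its call with each of the 6 pairs left out. Mast cell and basophil markers, 3 of 16 of them adjusted over the list alone (the IgE receptor genes Ms4a2 and Fcer1a, and Csf2rb2), had a median of -3.93 (camera 3.01e-08, and adjusted p = 0.225 with an estimated correlation). In N cultures the 46 genes had a median of 135 FPKM in MP, 11.5 in LT-HSC and 16.8 in ST-HSC, and 42 of them were lower in LT-HSC than in MP. Late granule genes went both ways at day 2, with S100a8 and Lcn2 higher in LT-HSC 2N than in MP 2N (1270 against 805 and 494 against 350 FPKM) and Camp and Ngp lower (1270 against 2780 and 799 against 1680).

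The comparison of N cultures with uncultured cells asks what differed between them without doxycycline. It cannot tell an effect of culture from a response already present in the uncultured cells when they were picked, which was not tested. In limma over 3 cell types, 911 of 12060 genes passed, 583 higher and 328 lower in culture, and 910 of them moved the same way in each type. The falls were led by immediate early genes, which stress and growth signals switch on within minutes. Atf3, a stress-response repressor, fell by 8.51 ± 0.852 log2 units (adjusted p = 0.00272), from 161.3 to 1045 FPKM to at most 7.41. The AP-1 subunits Fosb and Fos fell by 7.71 and 7.58 (adjusted p = 0.00144 and 0.0028) and Jun fell by 6.35 (adjusted p = 0.0018), the last from 97.2 to 141 FPKM to at most 1.54. The nuclear receptors Nr4a1 and Nr4a2 fell by 7.61 and 6.08, the G-protein regulator Rgs1 by 6.68, the chemokine Cxcl10 by 6.64 and the MAPK phosphatase Dusp1 by 5.70, while sphingosine kinase Sphk1, at 35.3 to 157 FPKM uncultured, was listed at 0 in every N library. Among the rises, Igfbp7, a secreted binder of growth factors, was listed at 0 in all 3 uncultured libraries and at 17.2 to 161 FPKM in N (adjusted p = 0.00272). The galactose-binding lectin Lgals3 rose by 4.70, and the calcium-binding S100a4 and S100a6 by 4.53 and 3.78 (adjusted p = 0.0308, 0.0187 and 0.0379). Rad1 of the DNA damage checkpoint, Mrps24 of the mitochondrial ribosome and Ppil5 of the cell cycle rose by 4.43, 3.91 and 3.84. The other rises named by rank were the small RNAs Snora43 and Mir671 and the mitochondrial transfer RNA gene mt-Tl1, all listed at 0 in the uncultured libraries. As mt-Tl1 was listed at 0 in the 2N libraries too, its rise was in the 4N libraries alone.

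The split of rises and falls followed the scaling. Median-of-ratios scaling gave 393 higher and 404 lower and moved the median difference of all genes from 0.173 to 0.00926; quantile normalization gave 389 and 352. Without ST-HSC 1 gene passed and all 20 genes named by rank lost their calls (adjusted p of 0.0654 to 0.217). Without LT-HSC 59 genes passed and 9 of the 20 lost theirs (0.0641 to 0.168), and without MP 1 lost its call (0.0921).

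As a list, 18 of 28 immediate early and stress genes fell and 0 rose (23 and 0 adjusted over the list alone; median -3.44; camera 7.86e-24, and adjusted p = 0.163 with an estimated correlation). HSC surface and signature genes had 6 of 31 lower and 0 higher, the same adjusted over the list alone (camera 2.28e-06, and adjusted p = 0.163 with an estimated correlation). They included the cytokine lymphotoxin beta (Ltb, -3.98), the lipid carrier Apoe (-3.95) and the membrane protein Pdzk1ip1 (-3.28). MAPK feedback genes had 3 of 12 lower (6 adjusted over the list alone; camera 8.31e-04, and adjusted p = 0.233 with an estimated correlation), the inhibitors Spry2 (-3.13), Spry1 (-2.80) and Dusp5 (-2.72). Interferon response genes had 4 of 30 lower (7 adjusted over the list alone; camera 0.00124, and adjusted p = 0.246 with an estimated correlation), with the factor Irf1 at -2.29. Of 28 TGF-beta genes, 2 fell, the SMAD repressors Skil (-3.29) and Tgif1 (-1.95; camera 5.08e-04, and adjusted p = 0.49 with an estimated correlation; 0.0698 without ST-HSC). Among 31 p53 targets 6 fell and 1 rose (8 and 4 adjusted over the list alone), among them the cell cycle inhibitor Cdkn1a (-3.73) and the stress genes Gadd45b (-3.78) and Gadd45a (-3.09). That list's median of 0.18 and mean of -0.39 differed in sign (camera 0.265).

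Oxidative phosphorylation genes had 16 of 50 higher and 0 lower (21 and 0 adjusted over the list alone; median 0.73; camera 1.1e-07, and adjusted p = 0.49 with an estimated correlation), among them the ATP synthase subunits Atp5g1 (1.71) and Atp5f1 (1.59) and the complex I subunit Ndufc1 (1.42). G1/S genes had 5 of 46 higher and 0 lower (12 and 0 adjusted over the list alone; median 0.97; camera 2.28e-06, and adjusted p = 0.49 with an estimated correlation), including Gins1 of the replication helicase (2.66), the chromatin remodeller Hells (2.07), the fork protein Tipin (2.00) and the flap endonuclease Fen1 (1.85). G2/M genes had 4 of 45 higher, the same adjusted over the list alone (median 0.56; camera 0.00204, and adjusted p = 0.49 with an estimated correlation), with the mitotic kinase Pbk at 2.31, cyclin Ccna2 at 1.81 and the chromosomal passenger Birc5 at 1.29.

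Between 2N and 4N, 42 genes passed in limma, 19 higher and 23 lower at day 4. The largest were small RNAs, pseudogenes and a mitochondrial transfer RNA, not protein-coding genes. The 5 rises named by rank, among them mt-Tl1 and the small nucleolar RNA Snord96a, were listed at 0 in all 2N libraries and at 46.6 to 348 FPKM in 4N. Ribosomal protein pseudogenes such as Rpl34-ps1 (37.3 to 81.5 FPKM in 2N) and Rpl28-ps1 (27.5 to 55.9) went the other way and were listed at 0 in all 4N libraries. Restricted to protein-coding genes, an alternative chosen after seeing the data, 0 genes passed. Among 51 tested cytosolic ribosomal protein genes 2 rose, Rpl38 (listed at 0 in 2N and at 17.7 to 30.1 FPKM in 4N) and Rps21 (1.76). The count was 0 without LT-HSC or without MP and 11 without ST-HSC, where 4 of the 10 named genes lost their calls (adjusted p of 0.0579 to 0.139). Small RNAs and pseudogenes also separated all day 4 blood libraries from the rest: 40 genes were above 0 in all 6 day 4 libraries and at 0 in the other 9, and 11 showed the reverse. Comparisons of D with N within a day do not cross this divide, while those of cultured with uncultured cells do; at day 2 alone, chosen after seeing the data, 42 genes passed for N against uncultured cells, 4 higher and 38 lower.

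The comparison of MP with both stem cell types, over 5 conditions, asks which differences persisted. In limma 50 of 12453 genes passed, 7 higher and 43 lower in MP. Ly6a (Sca-1), the surface antigen used to sort mouse stem cells, differed by -4.18 ± 0.589 log2 units (adjusted p = 0.0152). Myct1, a regulator of stem cell and endothelial state, had a difference of -4.55 ± 0.806 (adjusted p = 0.0398), with 380, 437 and 12.3 FPKM in uncultured LT-HSC, ST-HSC and MP. The lymphocyte-survival GTPase Gimap6 (-4.50), the neural cell-arrest gene Npdc1 (-4.14), the GTPase Gem (-3.59), the platelet receptor Pear1 (-3.47), the homeobox factor Nkx2-3 (-3.37) and the growth suppressor Ndn (-3.34) were also lower. Higher in MP were lipoprotein lipase Lpl (2.12, adjusted p = 0.041), the PIP3-binding Adap1 (1.76), the mitochondrial Chchd10 (1.51) and the lysosomal peptidase Dpp7 (1.35). Calls rested on few libraries: the count was 13 without the uncultured libraries, 2 without 2D and 1 without 2N or without 4N. All 17 genes named by rank lost their calls without 2D, 2N or 4N (adjusted p of 0.0763 to 0.238), 13 of them without the uncultured libraries (0.0506 to 0.122) and 6 without 4D (0.0532 to 0.137).

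By list, 5 of 24 stem and progenitor transcription factors were lower in MP and 0 higher (12 and 0 adjusted over the list alone; median -1.29; camera 4.73e-13, and adjusted p = 0.105 with an estimated correlation). These included the self-renewal factors Hoxa10 (-3.29), Mecom (-3.17) and Hoxa9 (-2.14). HSC surface and signature genes had 4 of 31 lower (15 adjusted over the list alone; median -1.77; camera 5.77e-14, and adjusted p = 0.105 with an estimated correlation). Among 11 endothelial markers 1 was lower (6 adjusted over the list alone; camera 3.57e-09, and adjusted p = 0.105 with an estimated correlation), the TGF-beta co-receptor Eng (-2.48). Epithelial genes had 3 of 25 lower (7 adjusted over the list alone; camera 1.43e-05, and adjusted p = 0.105 with an estimated correlation), among them the junction protein Marveld2 (-3.14) and the protease inhibitor Spint2 (-2.21). Myeloid differentiation genes had a median of 1.53 in MP (camera 1.27e-09, and adjusted p = 0.301 with an estimated correlation), yet none of 47 passed limma's threshold in either adjustment. The nearest were the monocyte factor Irf8 (2.45, adjusted p = 0.145) and the granulocyte factor Cebpa (1.99, adjusted p = 0.145). Uncultured LT-HSC shared the granule genes of uncultured MP, with Mpo at 7520 FPKM against 13200 in MP and 765 in ST-HSC, while Irf8 (7.4 against 122 in MP) was low in it.

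Between ST-HSC and LT-HSC, 3 genes passed in limma, each with an adjusted p of 0.0489. Flt3, the cytokine receptor gained as stem cells lose long-term self-renewal, was higher in ST-HSC by 3.54 ± 0.513 log2 units, at 11.6 to 106 FPKM against 0 to 3.39. The leukotriene C4 synthase Ltc4s was listed at 0 in every LT-HSC library and at 3.07 to 37.5 FPKM in ST-HSC, and the vesicle protein Syngr1 was lower (-3.29 ± 0.485). None of the 3 kept its call with any 1 condition left out (adjusted p of 0.0789 to 0.261), and the count was then 0, or 1 without the uncultured libraries. Macrophage and dendritic markers had 1 of 14 higher in ST-HSC (3 adjusted over the list alone; median 1.75; camera 1.92e-06, and adjusted p = 0.839 with an estimated correlation), and 3 of 27 JAK-STAT genes, the cytokine receptors Il1r1, Il2rg and Il10ra, were higher adjusted over the list alone (0 over all genes; camera 0.00408, and adjusted p = 0.85 with an estimated correlation; 0.127 without 4D). Megakaryocyte genes, with von Willebrand factor (Vwf) at -4.01 (adjusted p = 0.368), had a median of -1.03 (camera 0.0155, and adjusted p = 0.879 with an estimated correlation). That list's call ended without the uncultured libraries (0.0558), 2N (0.11) or 4N (0.646).

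D libraries set against uncultured cells hold culture and induction together. In limma 2167 of 12539 genes passed, 1262 higher and 905 lower. Median-of-ratios scaling gave 954 higher and 1145 lower and moved the median of all genes from 0.232 to 0.0475. Beyond genes given for D against N, neutrophil elastase Elane fell by 9.21 ± 1.62 (adjusted p = 0.00771), the calprotectin subunits S100a8 and S100a9 by 8.04 and 7.86 and the endotoxin co-receptor Cd14 by 7.31. The ficolin Fcnb, at 5.04 to 1652 FPKM uncultured, was listed at 0 in every D library, while Lgals3 rose by 7.13 ± 0.827 (adjusted p = 0.00182). Of 50 oxidative phosphorylation genes, 23 rose and 0 fell (34 and 0 adjusted over the list alone; median 0.82; camera 1.02e-09, and adjusted p = 0.327 with an estimated correlation). Of 45 G2/M genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone; camera 2.05e-05, and adjusted p = 0.327 with an estimated correlation), including cyclin Ccnb1 (2.64) and the ubiquitin enzyme Ube2c (2.25). Myeloid genes had 30 of 42 lower (37 adjusted over the list alone; camera 1.36e-22, and adjusted p = 0.276 with an estimated correlation), and 13 of 31 HSC surface genes fell and 2 rose (17 and 2 adjusted over the list alone; camera 2.12e-06, and adjusted p = 0.327 with an estimated correlation), with Gpr56 at -5.01. The count was 270 without LT-HSC, 1072 without ST-HSC and 1216 without MP. Without LT-HSC the calls of Elane (0.0952), Ctsg (0.1), S100a8 (0.0693), S100a9 (0.13) and Fcnb (0.089) ended, and without MP these and Prtn3 (0.0512 to 0.104).

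Fibroblasts, a connective tissue cell, were compared uncultured and at 2D and 4D; with no N libraries, culture and induction are held together here too. Of the 10 largest falls by rank, 8 were small or other RNAs listed at 0 at both days, such as the small nucleolar RNA Snord104 (451 FPKM uncultured). The other two were the imprinted RNA H19 and the growth factor pleiotrophin (Ptn). H19 went from 1433 FPKM to 0.805 at 2D and 1.67 at 4D, and Ptn from 1603 to 2.41 and 10.5. Among rises, Fetub went from 0 to 105 and 326 FPKM, the protease inhibitor Spink12 from 0 to 125 and 265, Mobp from 0 to 67.2 and 81.8, Stmn2 from 1.43 to 110 and 159, and the aldehyde dehydrogenase Aldh3a1 from 0 to 10.5 and 148. The other 5 of the 10 largest rises were Gm14706, Gm10196, Rpl13a-ps1, SNORA66.1 and Gm13368. With 1 library per condition no test was run; of 8842 genes at FPKM 10 or more in any of the 3 libraries, 296 were at least 4-fold higher and 401 at least 4-fold lower at both days (181 and 346 of them protein-coding). Median-of-ratios scaling gave 206 and 529, moving the median change of all genes from 0.326 to 0.0212, and quantile normalization gave 222 and 491.

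List medians were set against 10000 random lists matched on expression. Mesenchymal genes had a median change of -3.02, below all random lists, with 21 of 35 at least 4-fold lower at both days. The matricellular Ctgf went from 280 FPKM to 6.93 and 11.4, and the collagen crosslinker Lox from 643 to 17 and 72.1. Fibroblast markers had a median of -3.10 (16 of 27 at least 4-fold lower), including the chemokine Cxcl12 (91.7 to 1.40 and 2.77) and the matrix glycoprotein tenascin (Tnc, 871 to 22.9 and 40.9). Immediate early genes (-2.06), MAPK feedback genes (-1.84), TGF-beta genes (-0.87) and JAK-STAT genes (-1.04) also lay below all random lists. Ribosome biogenesis genes (1.15; nucleophosmin Npm1 from 189 to 911 and 937) and G1/S genes (1.01; the replication clamp Pcna from 8.26 to 37.5 and 34.8) lay above all of them. Epithelial genes had a median of 0.92 at percentile 96.76, 0.42 at day 2 and 1.49 at day 4, with Perp from 0.464 to 9.83 and 22.2 and Cdh1 (E-cadherin) from 0 to 1.34 and 2.47. In the small RNA and pseudogene divide, the uncultured fibroblast library followed the day 4 pattern in 27 of the 51 genes, and 2D and 4D in 9 and 8. Of the 40 genes above 0 only in day 4 blood libraries, 16 were above 0 in uncultured fibroblasts. The uncultured library thus differed from the D libraries along that divide, so the divide and the groups cannot be told apart here. From 2D to 4D, which lay on the same side, mesenchymal genes moved by 0.863 and fibroblast markers by 1.19.

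**Figure D4:**
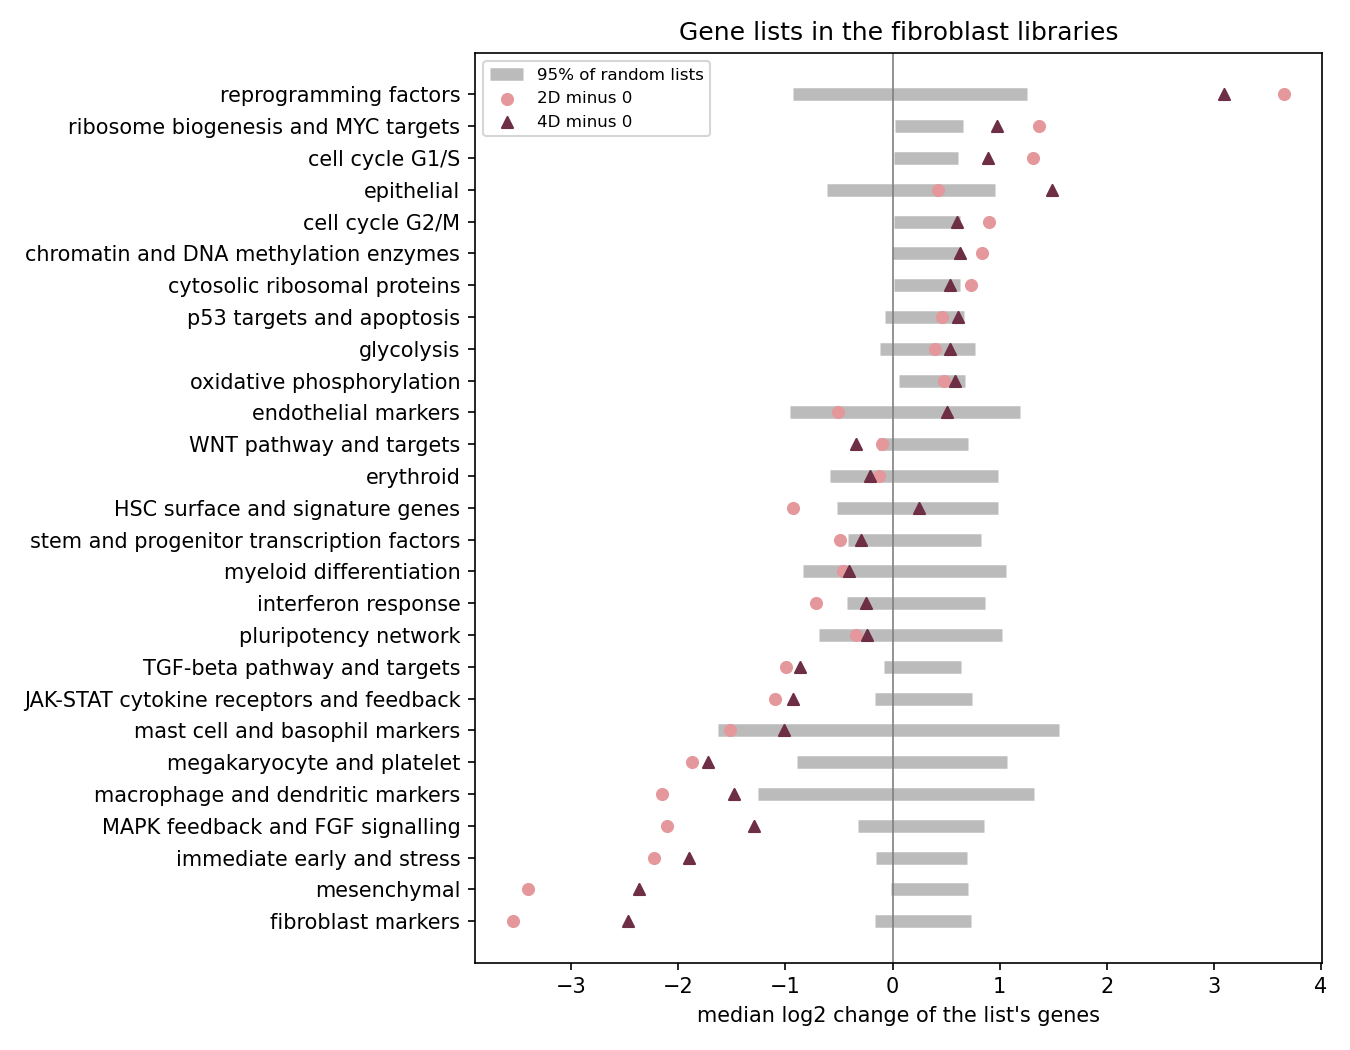
Median log2 change of each gene list (y axis) in fibroblasts from uncultured to 2D and to 4D (x axis, log2 units), with the range of 95% of random lists matched on expression in grey. The mesenchymal list (mean of both days -3.02) and the fibroblast markers (-3.10) lie below that range, and ribosome biogenesis genes (1.15) and G1/S genes (1.01) above it.

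Genes called in blood cells between D and N were followed in the fibroblast libraries, which are separate samples. Of 523 genes higher in blood D that were measured, 140 (26.8%) were at least 2-fold higher in fibroblasts at both days, against 17.3% of all 10788 genes. A further 60 (11.5%) were at least 2-fold lower, against 7.8% of all, so both directions were above the share of all genes. Mobp, Fetub, Stmn2, Spink12 and Aldh3a1 were among the 140. Of 324 genes lower in blood D, 93 (28.7%) were at least 2-fold lower in fibroblasts and 23 (7.1%) at least 2-fold higher, and the lower ones included the leukocyte actin-binding Lsp1, the antiangiogenic Serpinf1, Igfbp7 and Il4ra, named here after their values were seen.

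The last comparison tests whether the change from uncultured to D differed between fibroblasts and blood cells. Mesenchymal genes had lower changes in fibroblasts than in blood: of 35, 2 passed (20 adjusted over the list alone), with a median difference of -3.87 (camera 1.27e-17, adjusted p = 0.0341 with an estimated correlation, fry 0.00231). Ctgf (-4.82) was among those called over all genes. The median change in fibroblasts alone was -3.02, so part of the list difference was a rise in blood. Only 18 of these genes passed the expression filter in blood for D against N, and the others had little room to fall there. In limma 125 of 13235 genes passed, 56 higher and 69 lower. The change was lower in fibroblasts than in blood for Ptn (-8.63 ± 1.26, adjusted p = 0.0186), H19 (-8.42 ± 1.11, adjusted p = 0.0151) and the metalloproteinase inhibitor Timp1 (-8.24 ± 1.08, adjusted p = 0.0151). In fibroblasts alone H19 changed by -9.35 and Ptn by -8. Timp1 went from 479 FPKM to 40 and 93.7 there, a fall smaller than its difference, so the rest of its difference was a rise in blood. Cytosolic ribosomal proteins had 3 of 50 higher, Rpl32 (2.83), Rps15 (2.73) and Rps18, the same adjusted over the list alone, with a median of 0.62 (camera 1.21e-04, adjusted p = 0.0341 with an estimated correlation, fry 0.00305). Rps18 was listed at 0 in uncultured fibroblasts, but so are other genes that every cell uses in some libraries, with Rpl3 at 0 to 5.82 FPKM, Rps6 at 0 to 17 and Gapdh at 0 to 22.6 over all 18. Fibroblast markers had 4 of 24 lower (10 adjusted over the list alone; camera 2.42e-11, and adjusted p = 0.27 with an estimated correlation) and TGF-beta genes 3 of 38 (10 adjusted over the list alone; camera 2.11e-05, and adjusted p = 0.27 with an estimated correlation). The WNT receptor Fzd1 differed by -5.72 (1 of 28 pathway genes; camera 0.00525, and adjusted p = 0.119 with an estimated correlation). Among the genes above 0 in this comparison, Nkg7 and Cd37 were listed at 0 in all 3 fibroblast libraries and Cd14 at 1.695 FPKM or less, so their differences are falls in blood. In simulated data 42.4% of calls in this comparison were unchanged genes, and the small RNA and pseudogene divide applies here too. The uncultured fibroblast arm was a single library made by another method, so the p-values take their spread mostly from the blood libraries. Without MP 0 genes passed, without LT-HSC 2 and without ST-HSC 162; of the 20 genes named by rank, 20, 18 and 3 lost their calls (adjusted p of 0.0531 to 0.14).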

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

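Every result in this part is a difference between cell types in the same contrast; the test of LT-HSC against the other types, and the counts over other splits of the libraries, were chosen after the results were seen.

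The myeloid differentiation list fell further in MP than in the stem cells, by a median log2 difference of -3.49 that passed camera with the preset and the estimated correlation. In N cultures 42 of the 46 genes were lower in LT-HSC than in MP and 43 lower in ST-HSC (medians 11.5, 135 and 16.8 FPKM in LT-HSC, MP and ST-HSC), and a gene near 0 has less room to fall. Genes at 20 FPKM or more in N kept a median of 0.00526 and 0 of that level in LT-HSC at days 2 and 4, 0.00156 and 0 in MP, and 0.11 and 0.0192 in ST-HSC. Among these genes (14 and 8 in LT-HSC, 35 and 36 in MP) the fall was nearly complete in both LT-HSC and MP. They thus show no clear difference of MP from LT-HSC. The shares kept in ST-HSC were higher, over 22 and 23 genes. These sets differ between types, and 43 of the 46 genes started lower in ST-HSC than in MP. A similar low level in D would then give a higher share, so the shares cannot tell whether the starting level accounts for the difference from ST-HSC. Over single genes this interaction called 0 in limma, with 1018 at an unadjusted p under 0.05. The 15 splits of the 6 pairs are too few for a share under 0.05. The real split called 0 genes. The highest of the others, which grouped the LT-HSC pairs, called 4.

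In LT-HSC the D minus N difference departed from that of the other types in 4 genes. Reg3g, a secreted antibacterial lectin, rose further by 8.74 ± 0.766 (adjusted p = 0.0164), the annexin Anxa3 by 7.25 ± 0.84 (adjusted p = 0.0404) and the plexin Plxnb2 by 4.20 ± 0.426 (adjusted p = 0.0275), while carbonic anhydrase Car2 differed by -4.34 ± 0.501 (adjusted p = 0.0404). This test was added after the others, and 11 lists passed camera with the preset correlation and 0 with an estimated one. Other groupings of pairs, of mixed cell types, called up to 2 genes. The 15 groupings are too few for a share under 0.05, so chance is not excluded for the 4 genes. The same test for ST-HSC called 0 genes in limma (1004 at an unadjusted p under 0.05). It had 15 lists past camera with the preset correlation and 0 with an estimated one or with fry, among them stem and progenitor transcription factors (median 1.21, camera 3.84e-06, and adjusted p = 0.473 with an estimated correlation) and ribosome biogenesis genes (-0.96, camera 1.53e-10, and adjusted p = 0.488 with an estimated correlation).

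The change from uncultured to D differed between fibroblasts and blood cells in 125 genes, in the mesenchymal list by a median of -3.87 and in the cytosolic ribosomal proteins by 0.623. The mesenchymal genes were high in fibroblasts and low in blood from the start, so the floor at 0 limits how far they could fall in blood. Their median change in fibroblasts alone was -3.02, smaller in size than the difference. Some members therefore rose in blood, and the floor does not account for all of the difference. The ribosomal protein difference covers genes with many pseudogenes, the class that made up most of the genes dividing the day 4 blood libraries from the rest, and that divide and the groups cannot be told apart for it. Uncultured fibroblasts were a single library, so no spread was measured for that arm. The 4 splits are too few for a share under 0.05; the real one called 125 genes and the highest of the others 25.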

How the results depend on the processing

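The alternatives restricted to protein-coding genes, to day 2 only and to D against N without both ST-HSC pairs, and the counts over other splits, were chosen after seeing the data. Over all alternatives 180 counts stayed within 1.5 times the reported one and 80 did not. Of 140 named results, some of them not past the threshold as reported, 52 had the same status, called or not called, in every alternative. In no alternative was any reversed (0). With each block left out in turn, 18 of 20 named calls for D against N were kept and 14 of 20 for D against uncultured cells. In the other fits 0 of the named calls were kept throughout. Unless said otherwise the cause was not tested. Unknown depth limits all genes listed near 0.

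D against N, with 1099 genes, had 812 to 1124 under the 2 pseudocounts, the filters, both scalings and plain limma. It had 902 without both ST-HSC pairs and 1476 with no pair term. With fewer pairs it had 171 (day 2 alone), 169 (day 4 alone) and 308 (cell type as the unit), and in leave-one-out fits 529 (without MP day 2) to 1042. The lists at the smallest exact p went from 4 to 8 with list means. Lists past camera, 12 as reported, were 0 with an estimated correlation and 8 to 12 in leave-one-out fits. Of the 32 splits of the pairs, 1, the real one, gave 1099 genes and the highest of the others 0. That is the smallest share these splits can give. A flipped pair also adds its own difference to the spread, which lowers the other counts, so chance is not excluded.

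For the change from day 2 to day 4 the gene count stayed at 0 in limma (511 at an unadjusted p under 0.05), and the 10 splits, all of which gave at least as many, are too few (highest other 1). Its 11 lists became 0 with an estimated correlation, 0 with fry, 7 at a pseudocount of 5, 7 with no filter and 7 to 10 in leave-one-out fits. For MP against the stem cells, leave-one-out fits gave 0 to 1 genes (1 without ST-HSC day 4), and the 8 lists became 1 with an estimated correlation, 1 with fry and 3 (without MP day 4) to 11 in leave-one-out fits.

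N against uncultured cells, with 911 genes, had 352 with no filter, 257 with plain limma, 42 at day 2 only (41 shared) and 1 (without ST-HSC) to 793 in leave-one-out fits. Its 14 lists became 0 with an estimated correlation, 4 with fry and 9 to 15 in leave-one-out fits. D against uncultured cells, with 2167, had 532 at day 2 only (522 shared) and 270 (without LT-HSC) to 1216 (without MP) in leave-one-out fits; its 17 lists became 0 with an estimated correlation and 11 (without LT-HSC) to 15 in leave-one-out fits. For both, the real split alone of 27 gave as many genes (highest others 81 and 484). That is the smallest share these splits can give. The other splits add the difference of the uncultured libraries to the spread, which lowers their counts, so chance is not excluded.

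For 4N against 2N, 42 genes became 0 among protein-coding genes and 0 to 11 in leave-one-out fits. Its 2 lists became 0 with an estimated correlation, 0 with fry, 1 with quantile normalization and 0 to 5 in leave-one-out fits. Its 4 splits are too few (highest other 0).

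For MP against stem cells over all conditions, 50 genes became 19 and 16 at pseudocounts of 0.1 and 5, 2 with no filter, 17 with plain limma, 13 without uncultured libraries and 1 to 47 in leave-one-out fits. Its 18 lists became 0 with an estimated correlation, 8 with fry and 13 to 17 in leave-one-out fits. Of 100 splits, 2 gave as many genes, the real split (50) and 1 other (74), and another gave 42. The share is below 0.05, but a wrong split called more genes than the real one.

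For ST-HSC against LT-HSC, the 3 genes became 0 at a pseudocount of 0.1, with no filter, at a mean FPKM of at least 5, under both scalings and with plain limma, and 0 to 1 in leave-one-out fits. Its 5 lists became 0 with an estimated correlation, 0 with fry and 3 to 7 in leave-one-out fits. The 16 splits are too few (2 gave 3 genes, highest other 3).

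For fibroblasts against blood, 125 genes became 60 and 331 at pseudocounts of 0.1 and 5, 555 with no filter, 56 at a mean FPKM of at least 5, 203 with quantile normalization, 208 with plain limma, 64 among protein-coding genes, 0 at day 2 only and 0 (without MP) to 162 in leave-one-out fits. Its 15 lists became 2 with an estimated correlation and 4 with fry. In fibroblasts alone, 697 genes at 4-fold became 325 at a pseudocount of 5, which by construction shrinks changes at low values.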

Other observations

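All tests in this part were chosen after the patterns were seen, and the genes named were chosen after their values were seen.

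Some blood cell genes stood apart in the ST-HSC D libraries, as single values without a test. Coro1a, an actin regulator of leukocytes, stood at 2250 FPKM in both 2N and 2D of ST-HSC and at 3300 in 4N and 1910 in 4D. In LT-HSC it went from 4040 in 2N to 202 in 2D and from 3400 in 4N to 24.9 in 4D, and in MP from 1950 to 124 and from 3040 to 5.4. Procr, a receptor that marks the most primitive stem cells, stood in ST-HSC at 27.3 in 2N and 752 in 2D and at 0 in 4N and 391 in 4D; in LT-HSC it stood at 12.4 and 46.7 at day 2 and 9.22 and 0 at day 4, and in MP at 10.4 and 2.12, then 10.1 and 0. The stem cell factor receptor Kit stood at 16.7 and 28.9 in ST-HSC 2N and 2D, and at 7.68 and 23.5 in 4N and 4D, and was lower in D than in N in LT-HSC (26.9 and 5.87 at day 2) and MP (14.6 and 2.61). Cd34, another stem cell marker, was lower in D in ST-HSC too, from 596 to 220 and from 442 to 155, against 487 to 9.19 and 575 to 0 in LT-HSC.

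Between pairs, the correlation of the D minus N difference across genes (which are not independent replicates) ran from 0.195 to 0.623 with a median of 0.372. The number of genes at least 4-fold different between D and N ran from 798 higher and 556 lower in ST-HSC day 4 to 942 higher and 1302 lower in LT-HSC day 4 by their total; the most genes higher were in ST-HSC day 2 (1009).

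In ST-HSC D libraries stem cell genes stayed nearer to their N level than in the other types, while myeloid genes fell. The genes compared were those at 20 FPKM or more in each type's own N library, so the sets differ. At days 2 and 4 the stem cell genes numbered 21 and 21 in ST-HSC, 32 and 28 in LT-HSC and 12 and 11 in MP. The medians and quartiles below come from these unlike sets. Among members at 20 FPKM or more in N, stem cell list genes kept a median of 0.63 of their N level at day 2 and 0.838 at day 4, and myeloid genes 0.11 and 0.0192; in LT-HSC stem genes kept 0.274 and 0.0487, and in MP 0.166 and 0.0261. If an even share of cells did not respond, with that share at the myeloid upper quartile and the other cells at the highest stem upper quartile of LT-HSC and MP that day, stem genes could keep 0.792 at day 2, which leaves it open there, and 0.416 at day 4, below the lower quartile kept (0.587), which argues against it there. Weaker induction may still contribute, since Sox2 at day 4 was 39.1 FPKM in ST-HSC against 48.9 and 48.0 in LT-HSC and MP, but at day 2 it was 29.1 against 61.3 and 15.6, so it cannot be told apart. A response particular to ST-HSC also stays open, as the test of the difference called 0 genes in limma (1004 at an unadjusted p under 0.05; smallest adjusted p = 0.113).

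Uncultured LT-HSC held granule genes near the MP level. Elane stood at 13600 FPKM in LT-HSC, 44.7 in ST-HSC and 19200 in MP, and Camp, of late granules, at 1210, 1.26 and 928. RNA carried over from the MP library would bring its erythroid genes too, but these stood at a median ratio of 0.0147 to MP (quartiles 0.0123 to 0.017), and granule and myeloid genes at 0.74 (quartiles 0.59 to 1.02). Swapped labels are excluded by the stem cell lists, higher in LT-HSC than in MP by a median of 2.33 (bootstrap interval 1.35 to 2.85). Granulocyte precursors among the picked cells, with late granule genes at a median ratio of 1.31, and expression by the stem cells themselves both stay open. In LT-HSC 2N late granule genes were high, but they had moved both ways from the uncultured library. Lcn2 stood at 494 FPKM (22.1 uncultured), Ngp at 799 (235), Camp at 1270 (1210) and S100a8 at 1270 (4360). Mpo (16.8) and Elane (4.6) were low in LT-HSC 2N. Either explanation could give this. The labels give no sort gates and the genes were chosen for the pattern; the first is a candidate explanation only.

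A set of 51 genes divided the blood libraries by day 4 against the rest, 40 above 0 at day 4 alone and 11 at 0 there alone, against at most 4 and 6 in 100 random splits. In fibroblasts the uncultured library followed the day 4 pattern in 27 of the 51 genes and the day 4 library in 8 (exact McNemar p = 3.81e-06). Time in culture would not give this in these fibroblast libraries. They are single libraries of another cell type and method, so time in culture in blood stays open. Pseudogenes made up 80.4% of the set and 7.18% of all genes above 0 (exact binomial p = 7.76e-38). This is consistent with reads shared between pseudogenes and their parent genes being assigned differently in a set of libraries, such as another annotation or software version. Both p-values in this paragraph take the genes as independent units, and neither measures the spread between libraries. No biological explanation beyond time in culture was tested.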
